A study of Rattus norvegicus with 3 samples.

How the data were processed

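RNA from 3 cultures of FRSK cells, a rat keratinocyte line derived from fetal skin, was profiled on Affymetrix whole-transcript arrays, with 1 array for each culture. One culture received no peptide, one received Met-enkephalin (Met-ENK) and one received the fragment β-END(1-9) of β-endorphin. Both peptides were given at 100 nM for 24 h. Per the labels' protocols, the cells were grown in DMEM with 10% serum at 37 °C and 5% CO2, were plated at 1000000 cells per 10 cm dish, and gave total RNA that was extracted with TriPure and converted to biotin-labelled cDNA with the WT PLUS kit. The control is described as unstimulated, and whether it received vehicle or was kept for the same time is not given in the sources used here. The groups were taken from the sample titles. The series states 1 sample per condition.

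The deposited values are log2 signals, 1 per probe set and array. The submitters' processing notes name the Affymetrix Expression Console, the Transcriptome Analysis Console and RMA, a method that corrects background, quantile-normalizes the arrays and summarises the probes of each set. Versions, the annotation release and the genome build behind the probe sets are not given in the sources used here. The deposited log2 signals of the 3 arrays did not share 1 distribution over probe sets. RMA equalises the probe signals before each set is summarised, so it need not leave a common distribution over probe sets. The deposited signals had standard deviations of 3.42 for control, 3.35 for β-END(1-9) and 3.36 for Met-ENK over 23188 transcript clusters. Exactly equal values on 2 arrays were frequent, at 27.3% of clusters for Met-ENK and control, 29.9% for β-END(1-9) and control, and 27.2% for the 2 peptides, and 3658 clusters had 1 value on all 3 arrays. Many of the differences given in the report are therefore exactly 0, which makes medians of gene lists snap to 0 and makes small differences less informative than their decimals imply. The highest value, 19.93, was shared by 2 clusters and acts as a ceiling.

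The value table has 24834 probe sets, of which 1646 are control probe sets and were kept out of all gene comparisons. The platform annotation used here names 1 gene symbol for 15049 transcript clusters, several symbols for 0 and none for the other 8139, which are unnamed here rather than without a gene. All 15049 Entrez identifiers were found in the RefSeq annotation of assembly GRCr8, and 0 symbols changed through it. The named clusters stand for 15037 genes. For the 10 genes with several probe sets, the one with the highest mean over the 3 arrays was used. Genes absent from this naming, among them Krt5 and Krt10, are not analysed here. Genomic span, the distance from the start to the end of a gene, came from the GRCr8 annotation and was available for 15037 genes. It stands in only loosely for the length of the mRNA, and no coordinates are given because the build of the array annotation is not given in the sources used here.

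All comparisons are differences of log2 signals between 2 arrays. With 1 array per group there is no estimate of the spread between cultures, so no statistical test between groups was run and no p-value or standard error can be given. The number of arrays limits the precision of every value. Genes entered the counts when their mean over the 3 arrays was at or above the median of the named genes, a log2 signal of 6.41, which left 7519 genes. A gene was counted as higher or lower at a difference of at least 1.5-fold (0.58 on the log2 scale). The 23 background probe sets of the array lay between 2.51 and 7.57 with a median of 6.19 and had the same median, lowest and highest value on the 3 arrays, so genes near the lower limit of the filter cannot be separated from background by level.

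The overlap of the differences of the 2 peptides from the shared control array was set against 1000 simulated sets of 3 unchanged arrays, and against the overlap of independent lists. Gene lists were described by the median log2 difference of their members and by the percentile of that median among 10000 random lists of the same size, drawn from all named genes within 20 bins of mean level. A list was taken to stand apart below percentile 1 or above percentile 99. The 33 lists cover opioid receptors and peptides, keratinocyte genes, growth, stress, inflammation, metabolism, housekeeping and markers of other cell types. About 0.66 of 33 lists would fall outside these limits in each comparison if list members varied like randomly drawn genes. Lists whose genes vary together on an array can fall outside more often, so the percentiles are descriptions only.

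The filter, the thresholds, the lists and the rule for named genes were fixed before the data were examined. The rule takes, in each comparison, the 12 genes with the largest positive and the 12 with the largest negative difference among genes passing the filter. Of genes past 1.5-fold in 1 direction with both peptides it takes the 10 per direction with the largest smaller difference. It adds 2 to 4 leading members of each list that stands apart, the measured opioid receptor genes, and the keratins Krt5, Krt14, Krt1 and Krt10. Provisional symbols and symbols of large families of near-identical genes are counted but not named. Genes named outside this rule, such as Rps3, Cycs, Ndufv1, Aldh1a3, Penk, Pnoc, Ivl, Cst6 and Krt76, were chosen after their values were seen.

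Alternatives fixed at the same time were no filter, a filter at percentile 75, a new quantile normalization of the 3 arrays, removal of a loess trend on mean level (span of 0.3), centring of each array on its median, the mean over the probe sets of a gene, a threshold of 2-fold and the mean in place of the list median. After the data had been seen, 2 alternatives were added, the removal of the trend with genomic span and random lists matched on level (10 bins) and span (5 bins).

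The calculations were checked on simulated data. In 15037 simulated genes of the Met-ENK against control comparison, with the noise taken from the difference between the 2 peptide arrays, 50 genes were planted at each of 4 sizes. The 1.5-fold count recovered 38.0% of genes planted at 1.5-fold, 90.0% at 2-fold, 98.0% at 3-fold and 96.0% at 4-fold, while 308 of 7323 unchanged genes also passed the threshold. For β-END(1-9) against control, 5 of 200 lists of 30 unchanged simulated genes fell outside percentiles 1 to 99. These lists were drawn at random and the noise was shuffled across genes, so the rate does not cover lists whose genes vary together. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.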

Results

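The series holds 3 whole-transcript arrays of FRSK cells, a keratinocyte line from fetal rat skin. One array each was run for unstimulated control cells, for cells given Met-ENK and for cells given β-END(1-9), with both peptides at 100 nM for 24 h. Met-ENK is an opioid pentapeptide, and β-END(1-9) begins with the same sequence and carries further residues of β-endorphin. The question was which genes differ in keratinocytes after each peptide. There are no replicates, so each difference below is one between single arrays and has no replicate check. The arrays were alike in overall signal, with median log2 signals of 5.93 for control, 5.97 for β-END(1-9) and 5.96 for Met-ENK over 23188 transcript clusters. Across clusters, which are not independent replicates, the Pearson correlation was 0.996 for Met-ENK and control, 0.997 for β-END(1-9) and control, and 0.996 for the 2 peptides.

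The 9 measured genes of basal keratinocytes all passed the expression filter, against 2 of 17 epidermal differentiation genes and 2 of 7 simple and wound keratins. Krt14, a keratin of basal keratinocytes, had log2 signals of 16.70 on the control array, 16.63 with β-END(1-9) and 16.61 with Met-ENK. The differentiation keratin Krt1 had 5.77, 5.89 and 6.75 in the same order, all within the range of the background probe sets (2.51 to 7.57). Genes for the classical opioid receptors were also at background level. The µ receptor gene Oprm1 had 2.63 on the control array and 2.73 with either peptide. The δ receptor gene Oprd1 had 5.70 on the control array, 6.07 with β-END(1-9) and 6.15 with Met-ENK. The κ receptor gene Oprk1 had 3.70, 3.88 and 3.70 in that order, and the nociceptin receptor gene Oprl1 had 4.07, 4.07 and 4.55. Mrgprx3, of the Mas-related receptor family, had 4.11, 3.86 and 4.11. Signals above the background range came from the opioid growth factor receptor gene Ogfr (9.67, 9.71 and 9.67), which encodes a receptor for Met-ENK, from Ogfrl1 (10.72, 10.80 and 10.68) and from Ackr3 (9.16, 9.16 and 9.28), an atypical receptor that binds opioid peptides. Of the 8 measured genes of this list, 0 differed by 1.5-fold in any comparison, and the list median differed by 0.05 for Met-ENK and 0.06 for β-END(1-9) against control. Signals at background level do not show whether a receptor was present.

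Genes for ribosomal proteins and for the mitochondrial respiratory chain were lower on the Met-ENK array than on the control array. The 38 measured ribosomal protein genes were all lower (Rps3 by under 0.01), 13 of them by at least 1.5-fold, with a median log2 difference of -0.51 that lay below all 10000 random lists. Examples are Rpl19 (-0.93), Rpl13 (-0.91), Rps15 (-0.87) and Rpl11 (-0.85). Of the 34 measured genes of oxidative phosphorylation, 31 were lower, 11 of them by at least 1.5-fold, with a median of -0.41 that also lay below all random lists. Its leading members were Uqcrc1 of complex III (-1.18), Cox7a2 of cytochrome oxidase (-0.99), the complex I gene Ndufb5 (-0.95) and Ndufa4 (-0.91), whereas Cycs and Ndufv1 differed by 0. Housekeeping genes formed the remaining list that stood apart, with a median of -0.20 at percentile 0.765, and Hprt1 was the member at least 1.5-fold lower (-0.68), followed by Psmb2 (-0.58) and Pgk1 (-0.44). This list no longer stood apart after quantile normalization (median -0.10), with the list mean (-0.19) or among random lists matched on level and span (percentile 6.17). It shares Rplp0 and Sdha with the other 2 lists. The 399 probe sets named as positive controls on the array had a median difference from control of -0.23 with Met-ENK and -0.12 with β-END(1-9). For the 1153 named as negative controls it was 0.09 and 0.03.

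Single genes with the lowest values on the Met-ENK array relative to control were in part from the same processes. Uqcr11, a complex III subunit, differed by -1.59, and Atp5f1e, the epsilon subunit of ATP synthase, by -1.41. Mrpl53 (-1.54) and Mrpl12 (-1.51) encode proteins of the mitochondrial ribosome, and Etfb (-1.39) encodes a subunit of the electron transfer flavoprotein. The lowest value was that of Rabac1, a Rab-binding membrane protein, at -1.69. Cdkn3, a phosphatase of cyclin-dependent kinases, differed by -1.54, the carbonyl reductase Cbr1 by -1.51, the COP9 signalosome gene Cops9 by -1.47, the γ-secretase subunit Psenen by -1.37, the minor spliceosome protein Zcrb1 by -1.35 and Tmem254 by -1.33. All 12 of these lower genes also had short genomic spans, from 0.89 kb (Mrpl53) to 14.2 kb (Etfb), within the 2 shortest quintiles by span. Genes higher on the Met-ENK array than on the control array were led by Cybb (1.47), the catalytic subunit of the phagocyte NADPH oxidase, and by the muscle genes Tnnc1 (1.36), a troponin C, and Myl2 (1.15), a myosin regulatory light chain. Mfsd6 followed with 1.14 and Rgs17, a regulator of G protein signalling, with 1.02. Trem3 (0.99), Pitpnm2 (0.95), C14h4orf19 (0.94), Sipa1l2 (0.91), Cgref1 (0.90), Lrrc36 (0.89) and the ETS factor Fli1 (0.88) completed the 12. Of these 12 higher genes, 5 stayed within the background range on all 3 arrays, among them Cybb and Tnnc1, against 1 of the 12 lower ones. Myl2, at 12.41 on the control array and 13.56 with Met-ENK, lay far above it.

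Of 7519 genes, 52 were at least 1.5-fold higher and 453 at least 1.5-fold lower on the Met-ENK array than on the control array, so that 89.7% of these genes were lower. In the simulated check of this comparison, 308 of 7323 unchanged genes also passed 1.5-fold. At 2-fold the counts were 5 and 56. After a new quantile normalization they were 91 and 339, with 78.8% lower, and without the expression filter they were 448 and 633, with 58.6% lower. The lower genes were unevenly spread over gene sizes. In the quintile of genes with the shortest genomic span, 204 were at least 1.5-fold lower, against 117, 73, 36 and 23 in the following quintiles up to the longest. With the trend along genomic span removed, the ribosomal protein median was -0.27 and that of oxidative phosphorylation -0.24, both still below all random lists, and the housekeeping median was -0.051 and no longer stood apart.

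**Figure D1:**
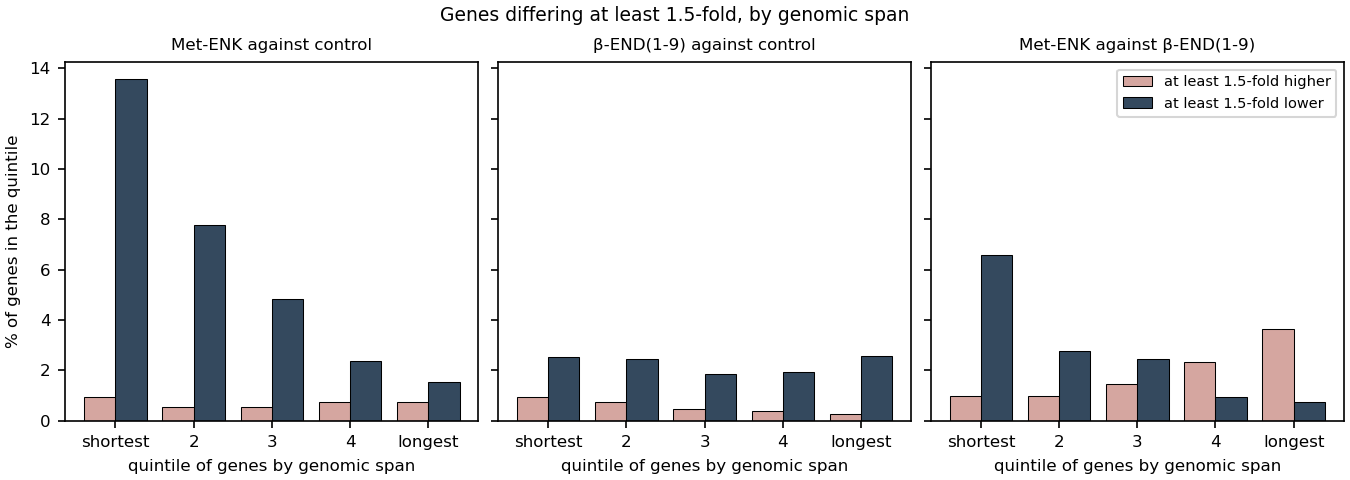
Percent of genes at least 1.5-fold higher (light bars) or lower (dark bars) in each quintile of the 7519 genes by genomic span, for the 3 comparisons between single arrays. For Met-ENK against control, 13.6% of the genes in the shortest quintile and 1.53% in the longest were lower, whereas β-END(1-9) against control gave 2.53% and 2.59%.

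Fewer genes differed between the β-END(1-9) array and the control array. Targets of the aryl hydrocarbon receptor, vitamin D and retinoids were the list that stood apart, with a median of 0.17 at percentile 99.95. Of its 16 measured genes, 10 were higher and 4 lower, with 1 in each direction past 1.5-fold. Cyp1a1, the cytochrome P450 known as a target of the aryl hydrocarbon receptor, was 0.96 higher, Cyp24a1, which inactivates vitamin D, 0.54, the receptor's repressor Ahrr 0.54 and the retinol dehydrogenase Rdh10 0.40, while Aldh1a3 differed by -0.77. Cyp1a1, Cyp24a1 and Ahrr lay within the background range, at 4.41, 5.55 and 6.56 on the control array, and 8 of the 16 genes passed the expression filter. With the mean in place of the median, 0.13, the list fell at percentile 98.57 and did not stand apart. The ribosomal protein genes had a median of -0.14 in this comparison, with 31 of 38 lower and 0 past 1.5-fold, at percentile 1.60, and the median was -0.033 after quantile normalization and -0.050 after loess scaling. Genes of oxidative phosphorylation had a median of -0.03 that turned to 0.061 after quantile normalization.

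Cybb was also the gene with the highest value relative to control on the β-END(1-9) array, at 1.76. It was followed by Bst2 (1.09), an interferon-induced membrane protein, Pcp4l1 (1.09), Pih1d2 (1.08), the G protein subunit gene Gngt1 (1.04), the steroid reductase Akr1d1 (1.00), Tnnc1 (0.98), Igsf21 (0.92), Gtdc1 (0.88), the odorant receptor Or4x13 (0.87), Prrg2 (0.83) and Olfm1 (0.83). Of these 12 genes, 7 stayed within the background range on all 3 arrays. The lowest values were those of St7l (-1.39), the chemokine Cxcl6 (-1.25), Plppr2 (-1.24), the dehydrogenase Dhrs1 (-1.22) and Alg5 (-1.21), an enzyme of N-glycan assembly. Dnajc30 (-1.19), the receptor P2ry10b (-1.14), Fn3krp (-1.13), the Golgi mannosidase Man1c1 (-1.12), Proser1 (-1.11), Mrpl12 (-1.11) and Pex7 (-1.11), a receptor for import into peroxisomes, followed. Of these 12 lower genes, 3 stayed within the background range on all 3 arrays (Plppr2, Man1c1 and Pex7). In all, 42 genes were at least 1.5-fold higher and 171 at least 1.5-fold lower than on the control array, which makes 80.3% lower. In the simulated check, 308 of 7323 unchanged genes passed 1.5-fold, more than these 2 counts together. Its noise came from the difference between the 2 peptide arrays and so contains any difference between the peptides. A new quantile normalization gave 62 and 114, with 64.8% lower, and without the expression filter the counts were 397 and 296, so that higher genes were then in excess (42.7% lower).

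**Figure D2:**
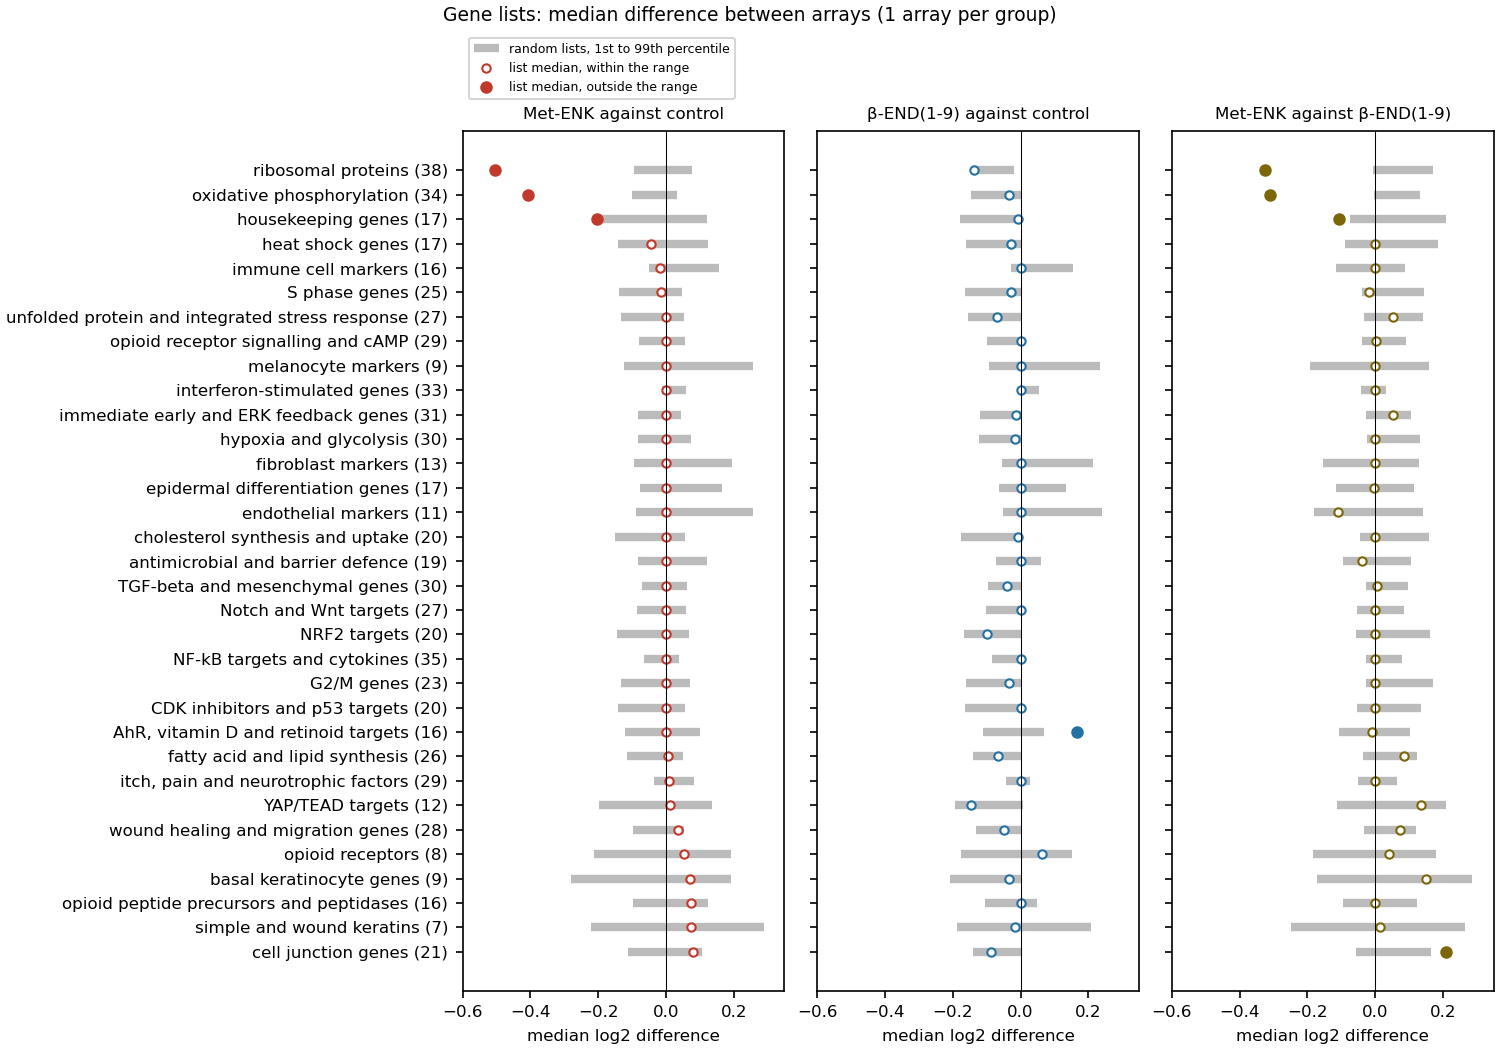
Median log2 difference of the 33 gene lists (measured genes in parentheses) in the 3 comparisons between single arrays. Circles are list medians, filled where they lie outside the grey bars, which run from the 1st to the 99th percentile of 10000 random lists matched on level. Ribosomal protein genes lie at -0.51 for Met-ENK against control and at -0.14 for β-END(1-9) against control, the latter being -0.033 after quantile normalization.

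Some genes differed from control in the same direction with both peptides. A set of 11 genes was at least 1.5-fold higher with both, led by Cybb, Tnnc1, the Myc antagonist Mnt (0.79 with either peptide), Pcp4l1, the chemokine Cxcl14 (0.81 with Met-ENK and 0.77 with β-END(1-9)), Myl2, Olfm1, Insl3, Adam4l1 and the calcium pump Atp2a3. With each array centred on its median, Atp2a3 was 0.57 higher with β-END(1-9) and so below 1.5-fold. The remaining gene of the 11 was the keratin Krt76, at 0.59 with either peptide, named after its values were seen and below 1.5-fold (0.56 with Met-ENK and 0.55 with β-END(1-9)) with that centring. Another 61 genes were at least 1.5-fold lower with both. The genes furthest down in both were Mrpl12, Cyp4v3 (-1.04 with Met-ENK and -0.97 with β-END(1-9)), Cxcl6, Cops9, Zcrb1, the mitochondrial ribosome gene Mrps7, Alg5, the isoprenoid enzyme Ggps1, Clip4 and the mitochondrial transporter Abcb8. Mnt, Adam4l1, Clip4 and Abcb8 had exactly equal signals on the 2 peptide arrays, so their 2 differences are 1 value and not separate measurements that agree. No gene went past 1.5-fold in opposite directions (0 genes).

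Both comparisons use the same control array, which alone makes their differences resemble each other. For 3 unchanged arrays the simulation gave 33.4 genes higher with both, with a 1st percentile of 22.0. It gave 33.2 genes lower with both, with a 99th percentile of 46. The 11 higher genes lay below these limits and the 61 lower genes above them. The simulated noise had random signs, so its 2 directions were balanced by construction. Of the observed genes past 1.5-fold, 89.7% were lower with Met-ENK and 80.3% with β-END(1-9). These limits therefore cannot separate the 61 genes from that general excess of lower genes. Independent lists would share 0.29 and 10.3. Across genes, which are not independent replicates, the 2 differences correlated at 0.46 against 0.50 in the simulation, and their covariance was 0.0277 against 0.0360. Both lay below the simulated 1st percentiles (0.48 and 0.0344). Of 4896 genes with both differences other than 0, 70.0% had the same sign, against 63.4% of all genes in the simulation. These 2 shares cover different sets of genes. Genes with exactly equal signals on the 2 peptide arrays, 21.5% of those passing the expression filter, cannot differ in sign. The 2 shares are therefore not comparable, and no conclusion is drawn from them. The simulated noise was taken from the difference between the 2 peptide arrays, so the simulated values also contain any difference between the peptides. In the simulation, whose 2 directions were balanced, a shared control array alone gave a higher correlation than observed. It also gave more genes higher with both but fewer genes lower with both. The single control array cannot be split, so how much of the overlap comes from it cannot be told.

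**Figure D3:**
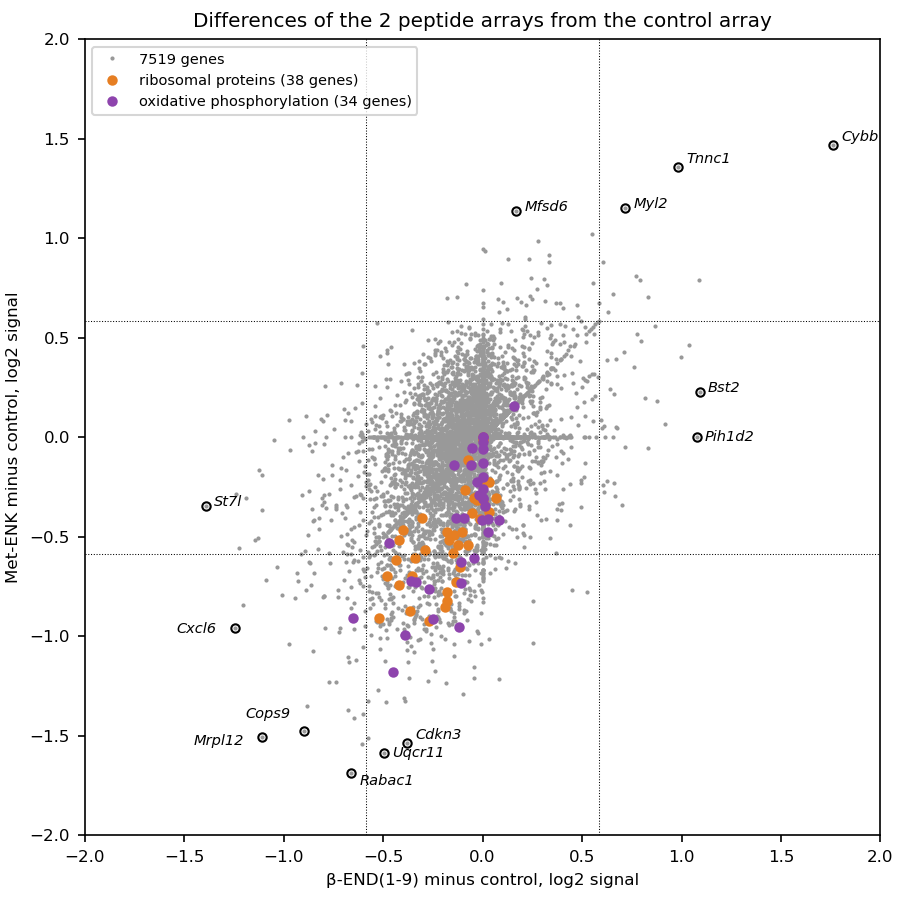
Log2 difference from the control array for 7519 genes, with β-END(1-9) on the x axis and Met-ENK on the y axis, where each point is 1 gene and dotted lines mark 1.5-fold. Ribosomal protein genes (orange) and oxidative phosphorylation genes (purple) lie mainly below 0 on the Met-ENK axis, and Cybb stands at 1.76 and 1.47.

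Apart from cell junction genes, which stood apart between the 2 peptides, the other gene lists did not stand apart in any of the 3 comparisons with random lists matched on level. In the list of opioid peptide precursors and peptidases, with 16 measured genes, the median difference from control was 0.07 with Met-ENK and 0.00 with β-END(1-9). Its member Penk, the precursor gene of Met-ENK itself, was singled out after its values were seen, and had a log2 signal of 10.05 on the control array, 9.49 with β-END(1-9) and 9.24 with Met-ENK, differences of -0.56 and -0.81. Pnoc, the nociceptin precursor gene, was the member past 1.5-fold with β-END(1-9) (0.78), at signals of 4.54 and 5.31 within the background range. Like Penk, the genes Pnoc, Ivl and Cst6 were chosen after their values were seen. Genes of opioid receptor signalling and cAMP had 0 of 29 members past 1.5-fold against control with either peptide. Basal keratinocyte genes had 0 of 9 past 1.5-fold, and simple and wound keratins 0 of 7. Krt6a, Krt6b and Krt16 of the latter list were not analysed. The same holds for 6 of the 15 listed basal genes and 16 of the 33 listed differentiation genes. Among 17 epidermal differentiation genes, 2 of them passing the expression filter, Ivl (0.61) and Krt1 (0.99) were past 1.5-fold higher with Met-ENK, and Cst6 past 1.5-fold lower with both peptides (-1.13 with Met-ENK and -0.67 with β-END(1-9)). Ivl, at 5.11 on the control array and 5.72 with Met-ENK, lay within the background range and fell below 1.5-fold under each of 3 other scalings (0.55, 0.58 and 0.58), and so did Cst6 with β-END(1-9) after quantile normalization (-0.58).

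Lists of growth and signalling genes had medians within 0.15 of 0. For Met-ENK against control, S phase genes (25 measured) had a median of -0.01 and G2/M genes (23) of 0.00, and for β-END(1-9) these were -0.03 and -0.03. Immediate early and ERK feedback genes (31) had 0.00 and -0.01, CDK inhibitors and p53 targets (20) 0.00 and 0.00, wound healing and migration genes (28) 0.04 and -0.05, TGF-β and mesenchymal genes (30) 0.00 and -0.04, YAP/TEAD targets (12) 0.01 and -0.15, and Notch and Wnt targets (27) 0.00 and 0.00. Among inflammatory lists, NF-κB targets and cytokines (35), interferon-stimulated genes (33) and antimicrobial and barrier genes (19) had medians of 0.00 with both peptides. Itch, pain and neurotrophic factors (29) had 0.01 and 0.00. Among stress and metabolic lists, heat shock genes (17) had -0.04 and -0.03, genes of the unfolded protein and integrated stress responses (27) 0.00 and -0.07, and NRF2 targets (20) 0.00 and -0.10. Hypoxia and glycolysis genes (30) had 0.00 and -0.02, cholesterol genes (20) 0.00 and -0.01, and fatty acid and lipid synthesis genes (26) 0.01 and -0.07. Markers of fibroblasts (13), melanocytes (9) and endothelial cells (11) had medians of 0.00 with both peptides, and immune cell markers (16) had -0.02 with Met-ENK and 0.00 with β-END(1-9). The expression filter was passed by 2 of the fibroblast, 1 of the melanocyte, 2 of the immune cell and 0 of the endothelial markers. Medians this close to 0 can change sign with the scaling, as those of NRF2 targets (0.011) and G2/M genes (0.049) with β-END(1-9) did after quantile normalization.

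The direct comparison of the 2 peptides, at the same dose and time, does not involve the control array. It uses the same Met-ENK array as the comparison of Met-ENK with control, so the 2 results are not independent. Ribosomal protein genes were lower with Met-ENK than with β-END(1-9), 38 of 38, with a median of -0.32 and 5 past 1.5-fold (Rpl11 -0.66, Rpl19 -0.65, Rpl35 -0.64 and Rpl34 -0.60 among them). Oxidative phosphorylation genes had a median of -0.31, with 29 of 34 lower and 0 higher, led by Ndufb5 (-0.83), Uqcrc1 (-0.73), Ndufa4 (-0.66) and Ndufa9 (-0.62). Both medians lay below all random lists, and with the trend along genomic span removed they were -0.11 and -0.20. Housekeeping genes had a median of -0.11 at percentile 0.50 (Hprt1 -0.68, Psmb2 -0.58), which became 0.017 without the span trend, and with the list mean it fell at percentile 1.19 and did not stand apart. Cell junction genes went the other way. Of 21 measured, 16 were higher with Met-ENK, 1 was lower and 2 were past 1.5-fold, and the median was 0.21 at percentile 99.87. With the filter at percentile 75 the median was 0.17 at percentile 94.8 and did not stand apart. Its leading members were Cldn7 (0.66), whose highest signal was 4.59 and within the background range, the tight junction scaffold Tjp1 (0.65, and 0.57 after loess scaling), the catenin Ctnnd1 (0.46) and the desmosomal cadherin Dsg3 (0.44). Against control, Tjp1 differed by 0.34 with Met-ENK and by -0.31 with β-END(1-9). Immediate early and ERK feedback genes, 20 of 31 higher and 6 lower with Met-ENK, but with 0 higher and 3 lower past 1.5-fold, had a median of 0.052 at percentile 93.4 and of 0.22 with the span trend removed, and lay at percentile 99.35 among random lists matched on level and span.

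**Figure D4:**
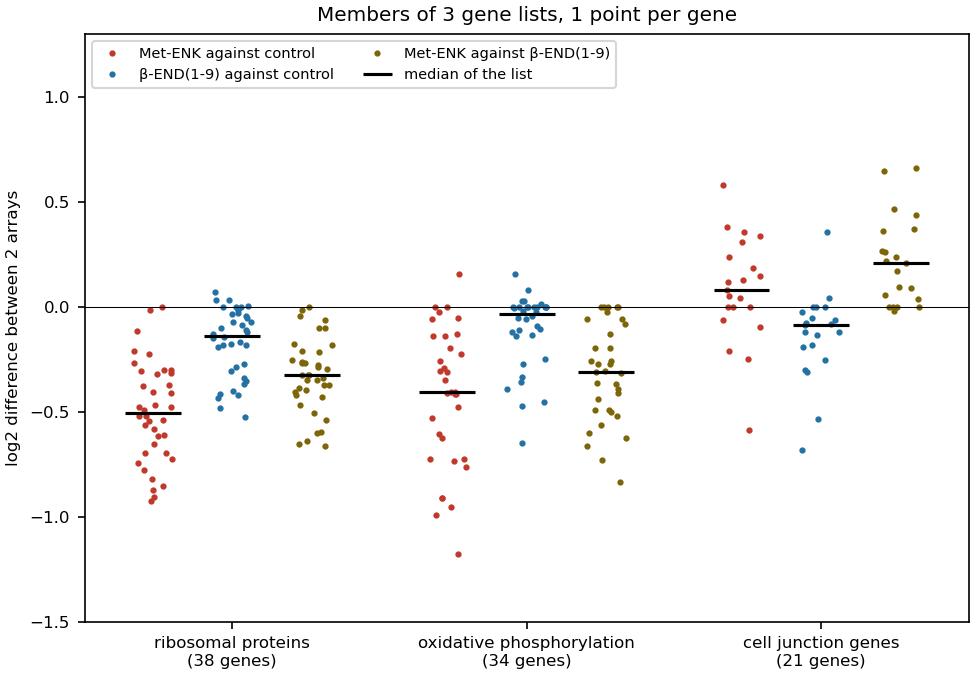
Log2 differences between single arrays for the members of 3 gene lists, 1 point per gene and a black bar at the list median. The medians of ribosomal protein genes are -0.51, -0.14 and -0.32 for Met-ENK against control, β-END(1-9) against control and Met-ENK against β-END(1-9), and those of cell junction genes are 0.08, -0.09 and 0.21. After quantile normalization the β-END(1-9) median of the ribosomal protein genes was -0.033.

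Genes with the highest values on the Met-ENK array relative to the β-END(1-9) array were the histone demethylase Kdm1b (1.10), the splicing regulator Ptbp2 (1.06), the kinesin Kif3b (1.06), Zfp445 (1.05), St7l (1.04), Ahdc1 (1.04), Entpd7 (0.99), Gnat1 (0.99), Mfsd6 (0.97), Man1c1 (0.96), Plppr2 (0.95) and Pitpnm2 (0.95). Most of these genes, Kdm1b, Mfsd6 and Pitpnm2 excepted, differed more from control on the β-END(1-9) array than on the Met-ENK array. Ptbp2 differed from control by -0.97 with β-END(1-9) and by 0.09 with Met-ENK, and Ahdc1 by -1.05 and -0.01, whereas Mfsd6 differed by 0.17 and 1.14. The lowest values were those of Adat1 (-1.30), a tRNA deaminase, the cyclin-dependent kinase inhibitor Cdkn2d (-1.30), the spliceosomal cyclophilin Ppil1 (-1.29), the muscarinic receptor Chrm3 (-1.22), Dad1 (-1.19) of the oligosaccharyltransferase, Plgrkt (-1.17), Cdkn3 (-1.16), the ubiquitin ligase Stub1 (-1.11), Uqcr11 (-1.09), Pih1d2 (-1.08), the interferon-inducible Ifi27 (-1.07) and Dnajc19 (-1.05). In all, 142 genes were at least 1.5-fold higher and 203 at least 1.5-fold lower with Met-ENK than with β-END(1-9), a share of 58.8% lower. The simulated check passed 308 of 7323 unchanged genes, but its noise was taken from this same difference, so it cannot judge these counts.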

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

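The test with random lists matched on genomic span, the test on gene size outside the named families, the test on the covariance of the 2 differences and the limit of 0.20 for reporting a spike-in were chosen only after the result was seen; the loess and quantile normalizations were planned, and what they would show was written down after the patterns were seen but before their values were. The rule for the covariance test was made stricter after its value was known, by also requiring the count of genes lower with both peptides to be no higher than the simulated 99th percentile, and under the first rule the shared control array would have counted as fitting.

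Signals outside the named genes also differed between the arrays. Among 3201 unnamed transcript clusters that passed the expression filter, 49 were at least 1.5-fold higher and 234 lower on the Met-ENK array than on the control array, and 30 were higher and 80 lower on the β-END(1-9) array. Of the bacterial spike-in probe sets, dap differed by 0.27 and thr by 0.32 between the Met-ENK and control arrays, while lys (-0.02) and phe (0.00) did not reach 0.20. On the control array lys was at 5.67 and phe at 6.85, within the background range, which limits what they can show. The probe sets bioB (0.05), bioC (0.00), bioD (0.05) and cre (0.02), all above that range, did not reach 0.20 either. Between the Met-ENK and β-END(1-9) arrays the differences were 0.35 for dap, 0.43 for thr and 0.20 for bioB. The 399 probe sets named as positive controls had a median difference of -0.23 between the Met-ENK and control arrays, -0.12 between the β-END(1-9) and control arrays and -0.11 between the 2 peptide arrays. The 1153 named as negative controls went the other way, with medians of 0.09, 0.03 and 0.02 in the same order.

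The pattern of most interest is the lower signal of ribosomal protein and respiratory chain genes on the Met-ENK array. A trend with genomic span does not account for all of it, since both list medians stayed at percentile 0 among random lists matched on level and span, nor does signal-dependent scaling, since the ribosomal protein median was -0.54 after a loess correction on level. A candidate explanation that stays open is that short mRNAs were under-represented in the Met-ENK library, because among highly expressed genes outside these families the median of the shortest quintile by genomic span minus that of the longest was -0.25, and genomic span is only a stand-in for mRNA length. A response of the cells to Met-ENK stays open as well and cannot be told apart from a library effect with 1 array per group.

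Another pattern is that more genes were lower than higher with both peptides among genes passing the expression filter, whereas without the filter 58.6% were lower with Met-ENK, 42.7% with β-END(1-9), and 133 were higher and 129 lower with both. The control array had the widest distribution of signals, and equalising the distributions by quantile normalization left 64.8% of the genes past 1.5-fold lower with β-END(1-9) and 78.8% with Met-ENK, so a wider distribution may account for part of the excess and the test decides no further. A deviation of the 1 control array that both comparisons share stays open, since the covariance of the 2 differences, 0.0277 against 0.0360 simulated, decides nothing. The simulated noise comes from the difference between the 2 peptide arrays and so contains any difference between the peptides, which also limits the simulated counts of genes higher or lower with both. Those simulated counts were also balanced between the 2 directions by construction, unlike the observed differences. A shared response of the cells to both peptides was not tested and stays open too.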

How the results depend on the processing

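The span-based alternatives were chosen only after the result was seen, and the other alternatives in this part were planned. No paired analysis was possible because each group has 1 array and the labels give no shared replicate numbers. Signal over background limits the genes higher with a peptide most, since 44.2% of those higher with Met-ENK and 50% of those higher with β-END(1-9) stayed within the range of the background probe sets on all 3 arrays, against 10.4% and 18.7% of the lower ones. Counts of genes follow the filter and the threshold by construction, because these set which genes are counted. Without a filter, 448 genes were higher and 633 lower with Met-ENK, 397 higher and 296 lower with β-END(1-9), 377 higher and 459 lower with Met-ENK than with β-END(1-9), and 133 higher and 129 lower with both. With the filter at percentile 75, the counts were 6 higher and 217 lower with Met-ENK, 3 and 25 with β-END(1-9), 48 and 82 between the peptides, and 1 and 10 with both, and the covariance of the differences was 0.0184. At 2-fold they were 5 and 56, 5 and 16, 6 and 16, and 1 and 1 in the same order. After quantile normalization, 91 genes were higher with Met-ENK, and 19 were higher and 32 lower with both, and the cause was not tested. Centring, loess scaling and averaging of probe sets moved no count by over 1.5 times.

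Ribosomal protein and oxidative phosphorylation medians stood apart under every alternative run in both comparisons that involve Met-ENK, whereas neither stood apart for β-END(1-9) against control in the planned analysis. Both comparisons that involve Met-ENK share its 1 array. Housekeeping genes no longer stood apart for Met-ENK against control with random lists matched on span (-0.20, percentile 6.17), quantile normalization (-0.10), the list mean (-0.19) or the span trend removed (-0.051), nor for Met-ENK against β-END(1-9) with span-matched lists (-0.11), the list mean (-0.11) or the span trend removed, where the sign turned (0.017). The cause was not tested beyond span. The list mean took targets of the aryl hydrocarbon receptor, vitamin D and retinoids to 0.13 and out of the limits, and the filter at percentile 75 left cell junction genes at 0.17 and percentile 94.8 and the former list with too few genes for a value. For single genes, 227 differences were recomputed under each of 5 alternatives, and 0 past 1.5-fold changed sign. Centring, loess, quantile normalization and the span correction took 4, 2, 4 and 12 of them below 1.5-fold and 5, 3, 3 and 2 others above it.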

Other observations

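The gene families in this part were chosen only after the result was seen, by symbol, as were the single genes, and percentiles come from random lists matched on level unless span is named.

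Other gene families were lower on the Met-ENK array than on the control array along with the ribosomal protein genes. Of 66 mitochondrial ribosomal protein genes, 57 were lower and 0 higher, 21 of them past 1.5-fold, with a median of -0.40 (percentile 0) and with Mrpl53, Mrpl12 and Mrpl55 (-1.33) in front. Their median with β-END(1-9) was -0.11 at percentile 0.370, and 4 were past 1.5-fold. Proteasome subunits had a median of -0.28, with 26 of 38 lower (Psma7 -0.88, Psmb4 -0.87, Psmb1 -0.81), and Sm and LSm proteins, which bind RNA in splicing and decay, had -0.29, with 17 of 22 lower (Snrpd2 -0.86). Genes with Nduf symbols, most of them of complex I, had -0.41, with 30 of 33 lower. All 75 ribosomal protein genes found by symbol had a median of -0.47 with Met-ENK, 70 of them lower, and of -0.13 with β-END(1-9) at percentile 0.160. The Met-ENK medians kept their sign under quantile, loess and median scaling. After quantile normalization the β-END(1-9) medians shrank to -0.030 for mitochondrial ribosomal genes and -0.024 for all ribosomal protein genes. Among random lists matched on level and span, the deposited values put the former at percentile 0.40 and the latter at percentile 4.89, where it did not stand apart. Among 20 NRF2 targets, whose list did not stand apart, 4 were past 1.5-fold lower with Met-ENK, the reductase Cbr1, Taldo1 (-0.92), the ferritin light chain Ftl1 (-0.80) and the peroxiredoxin Prdx1 (-0.61, and -0.45 after quantile normalization).

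Kinesin genes had a median of 0.10 for Met-ENK against control, at percentile 99.9, with 17 of 27 higher, Kif5c at 0.80 and the mitotic kinesin Kif11 at 0.54. Myosin heavy chain genes had a median of 0.13 for Met-ENK against β-END(1-9), with 18 of 26 higher (Myh9 0.54), and of 0.011 at percentile 87.8 for Met-ENK against control, where they did not stand apart. The 6 laminin genes had a median of 0.29 in that comparison, with 4 higher and 2 lower, and of -0.26 for β-END(1-9) against control, with 4 lower and 2 higher, whereas for Met-ENK against control it was 0.033 at percentile 73.2. With β-END(1-9) the lower members were Lamb3 at -0.32, Lamb2 at -0.41, Lama5 at -0.43 and Lamc1 at -0.19, and the higher ones were Lama1 at 0.33 and Lamc3 at 0.055. The medians that stood apart kept their sign under the same scalings. Among random lists matched on level and span, kinesins with Met-ENK against control stayed at percentile 99.53 and laminins with β-END(1-9) against control at 0.25, whereas myosins (98.52) and laminins (97.99) in the comparison of the peptides did not stand apart. With the span trend removed, the kinesin median was 0.060 and the myosin median 0.075, in the comparisons named above. Among basal keratinocyte genes, the integrin Itga6 was 0.49 higher with Met-ENK than in control, whereas Krt15 differed by -0.57. Genes of the ubiquitin-specific proteases, collagens, integrins, histones and zinc finger proteins did not stand apart in any comparison, and metallothionein genes were too few for a percentile.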
